A study of Mus musculus with 18 samples.

How the data were processed

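Chromatin accessibility was measured by ATAC-seq in nuclei of B cells and T cells taken by laser capture microdissection from fresh frozen spleen sections of C57BL/6J wild-type mice. In ATAC-seq a transposase cuts and tags open DNA, so that reads pile up where chromatin is accessible. Per the labels, the sections were tagmented in situ, the B and T cells were immunostained, and captures of 2 sizes were made: 10 tissue patches that together held about 1000 nuclei, or 100 nuclei captured one by one. The stained markers and the number of mice are not given in the sources used here. The 18 libraries fell into 4 groups: B patches (n = 5), T patches (n = 5), B 100 nuclei (n = 4) and T 100 nuclei (n = 4). Per the labels, libraries of a group were technical replicates and were read as paired-end 50 reads. No label tied a library to an animal, so libraries can share an animal, and p-values over libraries measure only the spread between these libraries and are too small as statements about mice.

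The authors deposited 1 table of whole-number counts for 27396 regions in 18 columns, and each column was matched to its library by the name in the labels. The deposited counts were raw, with totals from 319481 to 7343204 per library. Per the submitters' processing notes, bcl2fastq 2.20, Trimmomatic 0.36, Bowtie2 2.4.5, Picard, deepTools 3.5.2, SAMtools 1.14, MACS2 2.2.7.1 and R 4.1.0 were used on genome build mm10. Their roles, the calling of the regions, the treatment of duplicate reads and any shift for the transposase are not given in the sources used here. The reads carried no stated molecular identifiers, so counts are not independent molecules. Coordinates are printed as the file gives them, and whether the start counts from 0 or 1 is not given in the sources used here.

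Regions were assigned to genes with a gene table of assembly GRCm38.p6, which has the coordinates of mm10 but carries no strand, so transcription start sites could not be placed. The plan had been to use the nearest start site within 50 kb. In its place, each region was given the gene with the nearest of its 2 ends within 50 kb, which assigned 93.3% of the regions. The planned share of called regions near start sites and the planned motif enrichment were not run, since no strand and no genome sequence were used here. A share of regions within 1 kb of a gene end was added after the data were examined.

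Tests on counts used edgeR 4.0.16 in R 4.3.3: TMM factors, a quasi-likelihood F-test and Benjamini-Hochberg adjustment at 0.05. The same 25712 regions, those past filterByExpr with a minimum count of 10 over the 4 groups, were tested in each comparison. Each comparison was fitted on its own groups, and the difference between capture sizes on all 18 libraries. Standard errors of log2 fold changes were the fold change divided by the square root of F. Normalized CPM are counts scaled to a common library size with TMM factors, given as mean ± SD. The 16 gene lists, fixed before the data were examined, were tested with camera in limma 3.58.1 on voom values, with a preset inter-gene correlation of 0.01 and adjustment over the 16 lists. Single values per library were compared by exact permutation tests, two-sided unless stated, and adjusted over the 31 tests made. Library similarity was the Pearson correlation of log2 CPM with a prior count of 2.

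Named regions followed a rule fixed before the data were examined. It took the 8 highest and 8 lowest fold changes among called regions of at least median abundance whose groups did not overlap and whose gene was not a predicted one. It added up to 4 genes per list by smallest p, and a fixed set of marker genes with the region nearest a gene end, of which Cd4 had no assigned region. The text prints a part of these, and that part was picked after the values were seen. Alternatives were DESeq2 1.42.0, other scalings and filters, a joint fit, the replicate number as a block, thinned patches and each library left out.

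The count test was also tried, after a first run on the real data, on simulated data with the real means, library sizes and dispersions. The changed regions were drawn only from those at or above median abundance, so recovery at lower abundance was not measured. For B versus T in patches, over 25712 regions, 2 of 50 regions changed by 2-fold were recovered, 23 of 50 at 4-fold, 42 of 50 at 8-fold and 50 of 50 at 16-fold. For B versus T at 100 nuclei, over 25712 regions, 0 of 50 were recovered at 16-fold. For patches versus 100 nuclei, 10 of 50 were recovered at 16-fold in B and 2 of 50 in T. In the simulated data 0 of 100 unchanged lists passed camera in patches and 1 of 100 at 100 nuclei. A list changed by 2-fold passed in patches and did not at 100 nuclei. Regions were simulated independently of each other, so the check of lists cannot show false passes from correlated regions.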

Results

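The series compared accessible chromatin of splenic B cells and T cells cut from tissue sections, and asked it of captures of 2 sizes. B patches held 2713677 to 6553535 counts per library and T patches 2193837 to 7343204. B libraries of 100 nuclei held 547333 to 720555 counts and T libraries of 100 nuclei 319481 to 1076765. On the log10 scale the patch libraries lay 0.837 above the libraries of 100 nuclei (two-sided exact permutation p = 2.29e-05, the smallest the 43758 splits can give; adjusted p = 0.000177; n = 10 and 8).

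Patches gave reads in most regions and 100 nuclei in few. With every library thinned to 319481 counts, mitochondrial ones included and so not to equal nuclear depth, patches had reads in 21837 ± 1765 regions (SD, n = 10) and 100 nuclei in 7970 ± 2888 (SD, n = 8), a difference with a two-sided exact permutation p of 2.29e-05 (adjusted p = 0.000177). At full depth the regions with reads were 90.4% ± 8.86 in B patches and 89.5% ± 8.76 in T patches (SD, n = 5 each). They were 33.8% ± 4.99 in B and 25.9% ± 14.7 in T at 100 nuclei (SD, n = 4 each). T libraries 3 and 4 of 100 nuclei had reads in 3937 and 3296 regions.

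Mitochondrial DNA, which carries no nucleosomes and is cut readily, filled 4 of the regions. It took 27.6% ± 6.24 of counts in B patches and 19.4% ± 3.09 in T patches (SD, n = 5 each). At 100 nuclei it took 39.6% ± 7.45 in B and 30.3% ± 4.11 in T (SD, n = 4 each). In tests added after the data were examined, the share was lower in the 10 patch libraries than in the 8 libraries of 100 nuclei (two-sided exact permutation p = 0.00313, adjusted p = 0.0194). Within T cells this passed, at −10.93 points (exact p = 0.00794, adjusted p = 0.0246). Within B cells it did not, at −11.96 points (exact p = 0.0556, adjusted p = 0.0718), though the share differed there by no less. Between B and T it differed by 8.23 points in patches (exact p = 0.0476, adjusted p = 0.0642) and by 9.25 points at 100 nuclei (exact p = 0.114, adjusted p = 0.141), and neither passed adjustment.

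**Figure D1:**
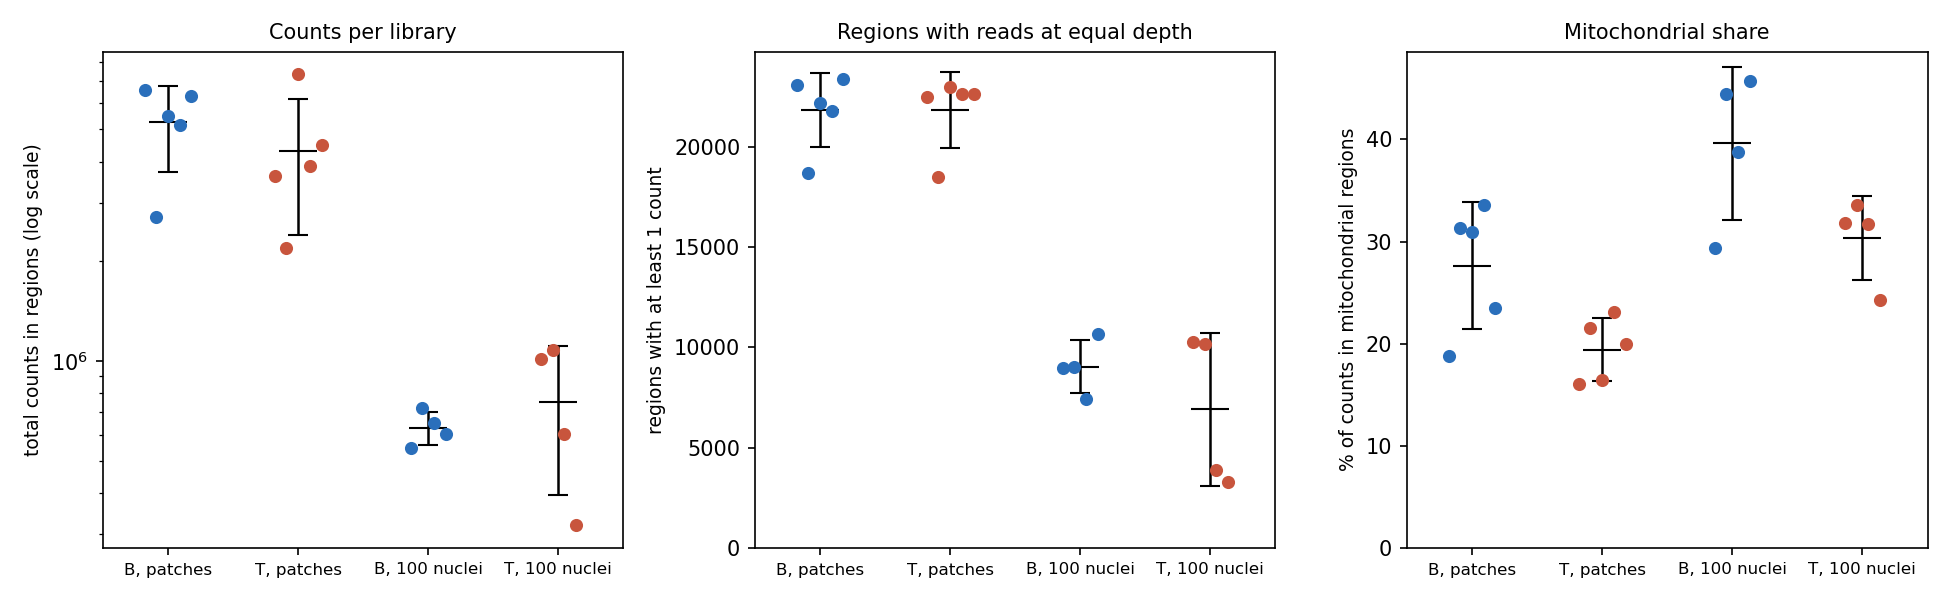
Total counts in regions (log axis), regions with at least 1 count after thinning to 319481 counts, and the percent of counts in mitochondrial regions, for each of the 4 groups. Points are libraries, and the bars give mean and SD (n = 5 for patches, 4 for 100 nuclei). All 10 patch libraries lie above all 8 libraries of 100 nuclei in the first 2 panels.

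In patches, libraries of a cell type resembled each other more than libraries of the other type. Across regions, Pearson's r averaged 0.637 within a cell type and 0.502 between B and T in patches, a difference of 0.135 (one-sided exact permutation p = 0.00794, the smallest possible; n = 10). At 100 nuclei the means were 0.291 and 0.266, a difference of 0.0251 (one-sided exact permutation p = 0.0286, the smallest possible; n = 8). There B libraries averaged 0.335 among themselves and T libraries 0.247, below the mean between B and T; without T library 4 the T libraries averaged 0.295 against 0.291 between B and T, so this order turned. Without any 1 of the 4 B libraries of 100 nuclei this difference was 0.00863 to 0.0128, with exact p from 0.2 to 0.229. Regions are not independent replicates.

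In patches, regions at genes of B cell identity were more accessible in B cells and regions at genes of T cell identity in T cells. At Cr2, the complement receptor of mature B cells, accessibility was 2.78 ± 0.45 (SE) higher in B on the log2 scale (87.0 ± 22.7 against 12.7 ± 9.14 normalized CPM, SD, n = 5 each; adjusted p = 0.00382; chromosome 1, 195176439 to 195176934, at an end of the gene). At Themis, needed in T cell development, it was −3.14 ± 0.47 (8.48 ± 4.32 against 74.3 ± 21.8; adjusted p = 0.00241; chromosome 10, 28668242 to 28668652, at an end of the gene). Of 25712 regions tested, 583 passed an adjusted p of 0.05, 314 higher in B and 269 higher in T, of which 581 were nuclear. The groups were fully apart in 8.03% of regions, where chance gives 0.794%. For B versus T at 100 nuclei they were fully apart in 1.18% of regions; the 2.86% that chance gives without ties is no measure there, since regions at 0 in both groups cannot be apart.

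The B cell identity list had 82 regions at 27 genes, of which 18 rose in B, at 15 genes, and 0 fell; adjusted over the list alone, 45 were higher in B and 1 lower. Its median log2 fold change was 1.90 (camera adjusted p = 3.53e-23; adjusted p = 0.00962 with an estimated correlation). At Ms4a1, which encodes CD20, the region was 3.38 ± 0.68 higher (72.3 ± 9.21 against 6.88 ± 6.83; adjusted p = 0.0113; chromosome 19, 11266050 to 11266484). At Fcrla it was 3.82 ± 0.62 higher (adjusted p = 0.00382; chromosome 1, 170928510 to 170928881, inside the gene). Beside Cd79b, part of the B cell receptor, it was 2.99 ± 0.53 higher (adjusted p = 0.00566; chromosome 11, 106308276 to 106308507, 2.83 kb outside the gene). Near Ebf1, a transcription factor of the B lineage, it was 3.02 ± 0.55 higher (adjusted p = 0.00674; chromosome 11, 44617105 to 44617422), while the region nearest an end of Ebf1 did not pass (1.56 ± 1.56, adjusted p = 0.827). The regions nearest an end of Cd79a and Pax5 had log2 fold changes of 2.51 ± 0.78 and 1.54 ± 0.62 and did not pass (adjusted p = 0.104 and 0.249).

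The T cell identity list had 82 regions at 28 genes, of which 14, at 12 genes, were lower in B and 0 higher; adjusted over the list alone, 40 were lower in B. Its median was −1.88 (camera adjusted p = 8.85e-20; adjusted p = 0.000259 with an estimated correlation). At Lef1 and Tcf7, which encode transcription factors of T cells, the called regions had log2 fold changes of −2.77 ± 0.46 (adjusted p = 0.00427; chromosome 3, 131157440 to 131157779, inside the gene) and −2.65 ± 0.48 (adjusted p = 0.00602; chromosome 11, 52268533 to 52268785, inside the gene). The regions the rule took nearest an end of Lef1 and Tcf7 did not pass (−1.26 ± 0.41, adjusted p = 0.128, and −2.51 ± 0.96, adjusted p = 0.216). At 22 kb from Satb1, a chromatin organizer, the value was −5.54 ± 1.06 (0.530 ± 0.838 against 27.8 ± 13.6; adjusted p = 0.00829). Inside Cd28, a costimulatory receptor, it was −4.25 (1.76 ± 2.29 against 34.9 ± 22.3; adjusted p = 0.028), and inside Skap1, an adaptor of T cell signalling, −4.30 ± 1.02 (adjusted p = 0.0283). The Cd28 call was lost without B library 1 or 4 or T library 2, 3 or 4 (adjusted p = 0.0521 to 0.0743). The Skap1 call was lost without B library 3, 4 or 5 or any T library (adjusted p = 0.051 to 0.0714), and its value was −6.63 without B library 1. The regions at Cd8a, Bcl11b, Lck and Cd3e had log2 fold changes of −2.60 ± 0.69, −2.08 ± 0.58, −1.82 ± 0.54 and −3.08 ± 1.42 and did not pass (adjusted p = 0.0511, 0.0613, 0.087 and 0.357). Without B library 2 Cd8a and Bcl11b passed (adjusted p = 0.0207 and 0.0221), as did Bcl11b without T library 2 (adjusted p = 0.00753), and without B library 1 the Cd3e value was −4.71.

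Regions of MHC class II genes, which present antigen to helper T cells, rose in B patches: 9 of 37 passed, at 5 genes, 0 fell, and 20 were higher adjusted over the list alone (median 1.83; camera adjusted p = 1.02e-12; adjusted p = 0.0439 with an estimated correlation). The regions were 2.10 ± 0.33 higher at H2-DMb2 (adjusted p = 0.00356), 2.14 ± 0.35 at H2-Ab1 (adjusted p = 0.00427), 2.19 ± 0.43 at Cd74 (adjusted p = 0.00932) and 2.52 ± 0.53 at H2-Aa (adjusted p = 0.0146). Of 67 regions at B cell receptor signalling genes, 9 rose, at 6 genes, and 0 fell, with 14 adjusted over the list alone (camera adjusted p = 1.85e-08; adjusted p = 0.0367 with an estimated correlation). Beside Cd180, a Toll-like receptor homologue, the region was 5.47 ± 0.96 higher (36.8 ± 16.4 against 0.708 ± 1.18; adjusted p = 0.00561; chromosome 13, 102689561 to 102689709, 3.84 kb outside the gene). At Vav2, Plcg2 and Nfatc1 the values were 3.34 ± 0.62, 1.65 ± 0.35 and 1.95 ± 0.46 (adjusted p = 0.00714, 0.0155 and 0.0269). The H2-Aa call was lost without B library 1 (adjusted p = 0.0571), and the Nfatc1 call without B library 1, 4 or 5 or T library 3 or 5 (adjusted p = 0.0521 to 0.0896).

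Of 57 regions at T cell receptor signalling genes 1 rose in B and 2 fell, with 1 and 3 adjusted over the list alone, and the list did not pass (camera adjusted p = 0.211). Inside Cd226, a receptor of T and NK cells, the log2 fold change was −3.81 ± 0.78 (adjusted p = 0.0131). Inside Cblb, a ubiquitin ligase known to restrain lymphocyte activation, it was 2.11 ± 0.51 (adjusted p = 0.032), a call lost without B library 1, 3 or 4 or T library 1, 3, 4 or 5 (adjusted p = 0.0519 to 0.12). In the list of T cell subset and effector genes 0 of 30 regions passed, with 4 lower in B adjusted over the list alone, and the list was lower in B (median −1.06; camera adjusted p = 5.42e-05; adjusted p = 0.0504 with an estimated correlation). Its region at Prf1, which encodes perforin, had a value of −2.05 ± 0.57 (adjusted p = 0.0639) and passed without B library 2 (adjusted p = 0.0446) or T library 2 (adjusted p = 0.0417).

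Of 23 regions at marginal zone B cell genes 3 rose, 0 fell, and 5 were higher adjusted over the list alone (camera adjusted p = 0.000375; adjusted p = 0.217 with an estimated correlation). Examples were Dtx1, at 3.15 ± 0.53 (adjusted p = 0.00466), and Cd9, at 2.23 ± 0.52 (adjusted p = 0.028). The Cd9 call was lost without B library 1, 3 or 4 or T library 3 or 4 (adjusted p = 0.0521 to 0.1). In the dendritic cell list 1 of 21 regions rose, 10.8 kb from Irf8, a factor that B cells also express, at 2.33 ± 0.40 (adjusted p = 0.00478; list camera adjusted p = 0.00678; adjusted p = 0.0631 with an estimated correlation). The other lists did not pass. Among them lymphocyte homing had 1 of 46 regions called, 15.8 kb from Cxcr4, a chemokine receptor, at 2.06 ± 0.52 (adjusted p = 0.0401; list adjusted p = 0.495). Macrophage and monocyte genes had 1 of 11, 9.2 kb from Adgre1, at 2.65 ± 0.70 (adjusted p = 0.0467; list adjusted p = 0.143). Both calls held in 2 of the 10 fits with 1 library left out. That at Cxcr4 was lost without B library 1, 3, 4 or 5 or T library 1, 3, 4 or 5 (adjusted p = 0.0664 to 0.129), and that at Adgre1 without B library 1, 2, 3 or 5 or T library 2, 3, 4 or 5 (adjusted p = 0.0572 to 0.13). Germinal centre and plasma cell, NK cell, neutrophil, erythroid and megakaryocyte, stroma and endothelium and housekeeping genes had 0 called regions of 22, 11, 4, 8, 8 and 39 (adjusted p = 0.211, 0.486, 0.475, 0.495, 0.735 and 0.486). In the NK cell list the median, 0.01, and the test differed in sign, and in the stroma list the mean, 0.05, and the test.

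Beyond the lists, the fixed rule ranked called regions of at least median abundance whose groups did not overlap. Regions inside Abcb10 and Gch1 were among its largest folds higher in B, at 4.84 ± 1.05 and 4.52 ± 0.95 (adjusted p = 0.0176 and 0.0142). Its largest higher in T were outside Npsr1 and Slc4a8 and inside N4bp2 and Gtf2i, at −6.36 ± 0.99, −5.40 ± 1.11, −5.30 ± 1.16 and −4.44 ± 0.94 (adjusted p = 0.00315, 0.0128, 0.0189 and 0.0155). Without B library 5, the only B library with reads at N4bp2, its fitted value was −10.47, which has no meaning as a size because all other B libraries had 0 counts, and without T library 1 Abcb10 was at 7.54. Calls were lost at Abcb10 without B library 1 or 4 (adjusted p = 0.0502 and 0.0723), at Gch1 without B library 4 (adjusted p = 0.051), at N4bp2 without T library 1 or 4 (adjusted p = 0.053 and 0.0538) and at Gtf2i without T library 4 (adjusted p = 0.0646). The region nearest Actb, a housekeeping gene, had a value of 0.92 ± 0.67 (adjusted p = 0.702), and its region with the smallest p −1.25 ± 0.39 (adjusted p = 0.101). All of these patch values rest on edgeR fits to technical replicates whose animals are not known, so their p-values are too small as statements about mice. For B versus T, patches, library size alone as scaling gave other proportions: the 594 calls split into 232 higher in B and 362 in T. A joint fit of the 18 libraries gave 0 calls. Leaving out any 1 library other than the patch libraries numbered 2 lowered the count: to 259, 291, 264 and 359 without B library 1, 3, 4 or 5, and to 347, 272, 334 and 376 without T library 1, 3, 4 or 5. Leaving out both libraries numbered 2, an alternative added after the data were examined, gave 1156.

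**Figure D2:**
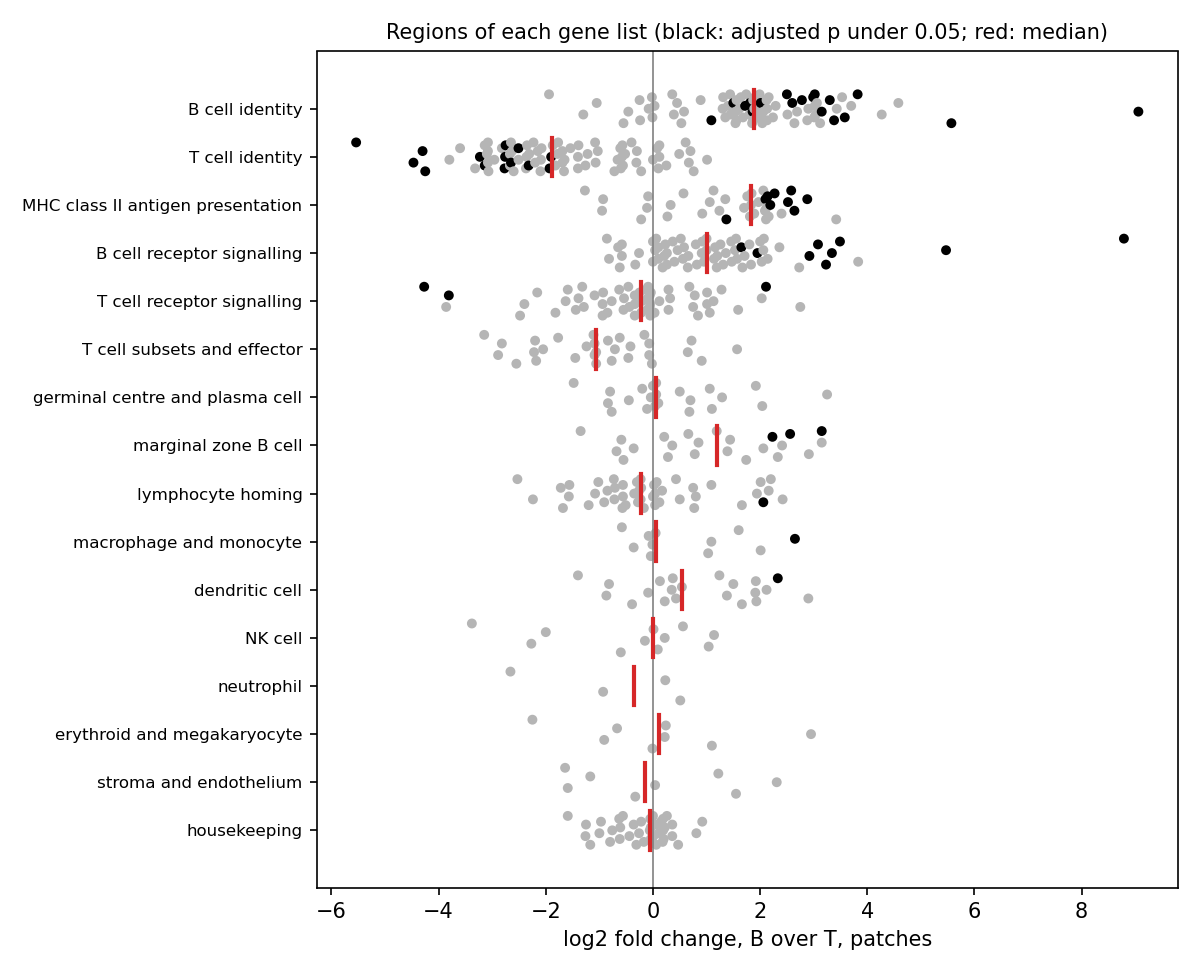
Log2 fold changes of B over T in patches for the regions of the 16 gene lists. Each point is a region, black where the adjusted p was under 0.05, and the red line is the list's median, 1.90 for B cell identity and −1.88 for T cell identity.

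At 100 nuclei, reads in identity regions followed the cell type in all 8 libraries, though no single nuclear region passed the test. The B cell identity regions took 0.389% ± 0.119 of nuclear counts in B and 0.116% ± 0.0725 in T, and the T cell identity regions 0.120% ± 0.0418 in B and 0.378% ± 0.0550 in T (SD, n = 4 each). B minus T list share, a measure added after the data were examined, was 0.269 ± 0.154 points in B and −0.262 ± 0.0916 in T (two-sided exact permutation p = 0.0286, the smallest possible; adjusted p = 0.0422). Reads at Cr2 were present in 4 of 4 B libraries and 0 of 4 T libraries, at the Pax5 region in 4 and 0, and at the Cd8a region in 0 and 2. A count of 0 at these depths does not show absence.

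The edgeR test at 100 nuclei called 4 regions, the 4 mitochondrial ones, all higher in B, and 0 nuclear regions. Of the regions tested, 1413 had an unadjusted p under 0.05. The 4 called regions lie on the same mitochondrial genome and are not separate results. The mitochondrial share per library did not pass between B and T at 100 nuclei (exact permutation adjusted p = 0.141). For B versus T, 100 nuclei, DESeq2 called 0, with 2151 under 0.05, and on simulated data the test recovered 0 of 50 regions changed by 16-fold. B cell identity was higher in B (camera adjusted p = 0.000155), T cell identity lower (adjusted p = 1.36e-07) and MHC class II higher (adjusted p = 0.00371); all have adjusted p = 0.494 with an estimated correlation. The other 13 lists did not pass. Among them marginal zone B cell genes (camera adjusted p = 0.0648) passed without B library 1 (camera adjusted p = 0.0429). The p-values share the limit on animals given above; a joint fit gave 6955 calls, and leaving out B library 2 or 4 left 2 calls.

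Regions called in patches pointed the same way at 100 nuclei. Of 536 called nuclear regions with reads at 100 nuclei, 477 had the same sign, 89.0% (exact binomial interval 86.0 to 91.5%). The regions come from the same 8 libraries and are not independent. The interval is therefore too narrow, and 50% is no safe measure of chance. Relabelling the 8 libraries in all 70 ways gave at most 80.2% otherwise (one-sided exact permutation p = 0.0143). The share was 91.3% of 299 regions higher in B and 86.1% of 237 higher in T. Across 21780 regions, which are not independent, the log2 fold changes of the 2 capture sizes had Pearson's r = 0.323 and Spearman's rho = 0.279.

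**Figure D3:**
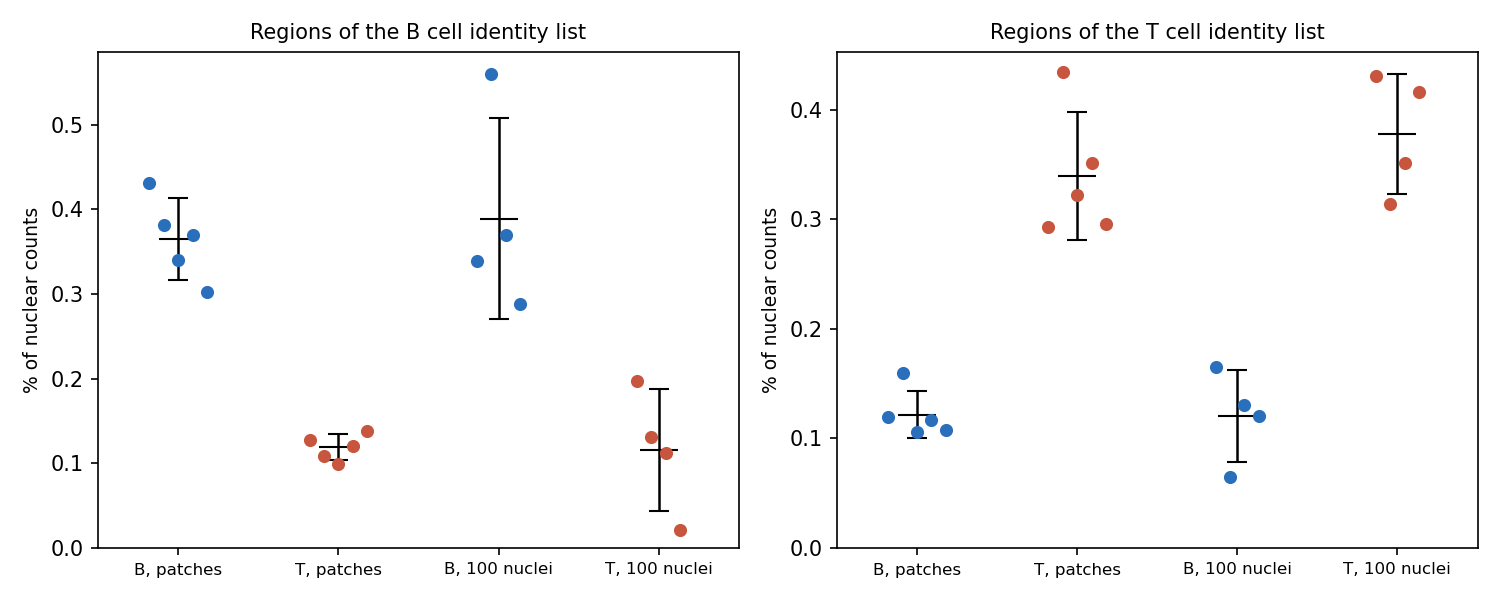
Percent of nuclear counts in the regions of the B cell identity list (left) and the T cell identity list (right) for each of the 4 groups. Points are libraries, bars give mean and SD (n = 5 for patches, 4 for 100 nuclei). B libraries average 0.365% in patches and 0.389% at 100 nuclei in the left panel, and T libraries 0.119% and 0.116%.

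The difference between B and T was not shown to depend on the capture size at any region. The edgeR test of that difference called 0 of 25712 regions, with 6968 (27.1%) at an unadjusted p under 0.05. Of the 16 lists 0 passed. The edgeR test pooled the spread of all 18 libraries, as did the joint fit that ended every B versus T call in patches. Its power was not simulated, so the 0 does not show that B and T differed alike in both sizes. For the difference of B versus T between capture sizes DESeq2 called 3144, loess offsets 1473, and leaving out T library 1 or 2 of 100 nuclei gave 419 and 97, leaving out T library 3 or 4 gave 7 and 10, and B library 2 or 3 of 100 nuclei 11 and 10. The identity lists took similar shares in both capture sizes. In B cells the T cell identity share was 0.122% ± 0.0218 in patches and 0.120% ± 0.0418 at 100 nuclei (log2 difference 0.08, interval −0.45 to 0.85; exact permutation p = 0.865). In T cells the B cell identity share was 0.119% ± 0.0153 and 0.116% ± 0.0725 (log2 difference 0.41, interval −0.61 to 2.04; exact permutation p = 0.738). The intervals are wide, so a difference was not detectable rather than absent.

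Between patches and 100 nuclei, nearly all called regions were higher in patches, in both cell types and across gene lists. In B cells 3579 of 25712 regions passed, 3576 higher in patches and 3 lower, and in T cells 7207, 7204 higher and 3 lower. The rule named, among others, Xpr1, Lsm6 and Mcur1 in B. Xpr1 had 46.0 to 137 normalized CPM in the 5 patch libraries, Lsm6 97.9 ± 24.7 and Mcur1 86.5 ± 23.5 (SD, n = 5), and all had 0 in all 4 libraries of 100 nuclei (adjusted p = 0.0283 for each). It named Irak4, a kinase of Toll-like receptor signalling, Dut and Mia2 in T, with 180 ± 37.6, 165 ± 38.7 and 129 ± 48.3 in patches and 0 in the 4 libraries of 100 nuclei (adjusted p = 0.012 for each). Of the T cell identity regions 16 of 82 were higher in B patches, and of the B cell identity regions 25 of 82 in T patches. Of their own type's regions 7 of 82 were higher in B patches and 16 of 82 in T patches. Of all tested regions 13.9% passed in B and 28% in T, so these list counts alone do not show an excess. Relative to all regions, camera put the other type's list lower in patches, and neither passed. The camera adjusted p was 0.779 for T cell identity in B and 0.0533 for B cell identity in T. In B 0 lists passed, and in T the erythroid and megakaryocyte list did (camera adjusted p = 0.0173; adjusted p = 0.897 with an estimated correlation; its median was 0.02, against a lower direction in the test). The limit on animals holds here too. Loess offsets gave 0 calls in both cell types, the joint fit 0 in B, and leaving out B patch library 1, 3 or 5 gave 0.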

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

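The tests of depth, of copied fragments, of missing reads, of scaling and of other cells were chosen after their results or related values were seen, and the tests of shared detection and of other splits before.

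Of 116 groups of libraries tested for a single value far from the rest, 16 held one. The threshold gives about 5% by chance for normally distributed values. Several groups lay near the floor, as at N4bp2, where the other B patch libraries had 0. The groups also share libraries, so 5% is no safe measure of chance here. T patch library 2 had reads in 74.2% of regions, against 91.3 to 96.4% in the other 4. It had 18485 regions with reads once thinned to 319481 counts, mitochondrial ones included. B patch library 2 had reads in 75.4% of regions and in 18714 once thinned. These were the lowest values of its group, but they fell short of the outlier threshold. T patch library 3 had a median count of 109 in regions with reads. B patch library 2 had a T cell identity share of 0.159%, against 0.105 to 0.119%. Among the T patch libraries, single values in normalized CPM stood apart at Cd180 (2.78, library 3), Abcb10 (5.34, library 1), Npsr1 (134, library 2), Ebf1 (36.9, library 5), Lef1 (112, library 2) and Plcg2 (48.6, library 4). Among the B patch libraries they did at Slc4a8 (2.93, library 4), N4bp2 (4.48, library 5), Skap1 (9.46, library 1), Satb1 (1.99, library 5), Cd226 (9.61, library 1) and Bcl11b (29.0, library 2).

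At 100 nuclei few regions had reads, and those held high counts. Lower depth alone was argued against: patch libraries thinned to the nuclear total of the library of 100 nuclei with the same type and number had at most 28.7% of regions at 0, and any patch library of the same type at most 32.8%, while libraries of 100 nuclei had 60.0 to 88.0%. A shared subset of open regions was argued against only among regions of like abundance in patches. Pairs of libraries of a cell type were set against independent detection within narrow classes of that abundance. They had reads in common at 1.03 times the number so given (range 1.02 to 1.06 over the pairs). A shared subset set by abundance itself would not show in this test, so it stays open. PCR copies of few starting fragments stay open. Regions with 3 counts or fewer made up 5.97% of regions with reads (range 4.47 to 8.14%) against 22.9% (10.3 to 29.8%) in thinned patches, which restates the pattern and decides nothing. No biological explanation was tested beyond the shared subset.

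Calls between patches and 100 nuclei were nearly all higher in patches. Reads missing by chance at 100 nuclei stay open: 98.4% of such calls in B and 99.6% in T had reads in at most 1 of the 4 libraries of 100 nuclei, but the call itself asks for few reads there, so this decides nothing. Scaling of the libraries stays open too. With offsets that follow abundance the median fitted log2 fold change moved from 1.33 to −0.86 in B and from 2.07 to −0.64 in T. The calls fell to 0 in both. Such offsets take out any broad shift between libraries, whatever its cause, so this decides nothing. Other cells within the patches cannot be told apart from these, because the interval of the other type's list share reached 2.04 on the log2 scale. For the counts, 1 of 100 splits of the B libraries, the real one, gave as many calls (3579, highest other 4). In the T libraries it was 1 of 100 too (7207, highest other 2495). This argues against a chance division of these libraries. All patch libraries lay above all libraries of 100 nuclei in depth and detection. The real split could stand out for that alone, so this decides nothing about accessibility.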

How the results depend on the processing

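The alternatives that left out mitochondrial regions or doubted libraries, the assignment by overlap, and the leave-one-out values of similarity, detection, agreement, list shares and mitochondrial percent were added after the data were examined. Where no cause is named, the cause was not tested. The agreement from calls at 100 nuclei gave no value, since no nuclear region was called there; the promoter and motif alternatives were not run.

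B versus T, patches (583) gave 2112 calls with DESeq2, 0 in the joint fit, 1156 without the patch libraries numbered 2, and 259 to 673 with 1 library left out. Thinned to the totals of 100 nuclei, 4 libraries each gave 616. B versus T, 100 nuclei (4): DESeq2, a filter on the 8 libraries and leaving out mitochondrial regions each gave 0, the joint fit 6955, and 1 library left out 2 to 4. The difference of B versus T between capture sizes (0) became 2 with DESeq2 size factors, 1473 with loess offsets, 3144 with DESeq2, 92 without both shallow T libraries, and 0 to 419 with 1 library left out. The patches versus 100 nuclei, B, count (3579) gave 2230 with DESeq2 size factors, 0 with loess offsets and in the joint fit, and 0 to 4973 with 1 library left out. The patches versus 100 nuclei, T, count (7207) gave 0 with loess offsets, 3057 without both shallow T libraries, and 4928 to 9035 with 1 library left out.

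Replicate numbers were shared between groups. Across regions, same-numbered libraries were barely correlated in their deviations (−0.0111 to 0.0339), and most libraries correlated best with another number. In depth and detection, though, the patch libraries numbered 2 went together. They had the lowest totals of their groups, 2713677 counts in B and 2193837 in T. They also had the fewest regions with reads, 75.4% and 74.2%. Whether the number marks a shared step was not tested. With the number as a block, B versus T, patches, gave 215 calls and B versus T, 100 nuclei, 0, and patches versus 100 nuclei gave 3 in B and 2 in T; the block leaves fewer degrees of freedom.

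At 100 nuclei the B and T cell identity lists both had adjusted p = 0.494 with an estimated correlation. With fry the adjusted p was 0.688 for T cell identity and 0.00438 for B cell identity. Fry, however, put every list but T cell identity higher in B there. Lists of other cell types passed it too, such as macrophage and monocyte (0.014) and neutrophil (0.0342). The fry value of B cell identity is therefore not particular to that list. With 1 library left out the adjusted p ran from 8.26e-05 to 0.00434 for B and from 2.44e-08 to 3.72e-05 for T; in patches from 5.2e-24 to 9.01e-20 and from 3.43e-20 to 8.62e-17. Similarity ran from 0.00863 to 0.0477 at 100 nuclei and from 0.125 to 0.146 in patches. Depth ran from 0.793 to 0.871, detection from 13200 to 14256 regions, agreement from 86.3 to 89.5%, the list share difference from 0.456 to 0.565 points, and the mitochondrial difference from −13.0 to −9.91 points.

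Fry, which tests lists without comparing them with other regions, turned the direction to higher in patches for these lists, by its adjusted p. In B they were T cell identity 0.000111, MHC class II 0.000502, B cell receptor 0.000215, T cell receptor 3.33e-05, T cell subsets 0.00479, marginal zone 0.00255, NK 0.00786, erythroid 0.0262 and stroma 0.0105; neutrophil turned too but passed neither test (0.571). In T they were B cell identity 0.00121, T cell identity 0.000526, MHC class II 0.00153, B cell receptor 0.00386, dendritic 0.000423, neutrophil 0.0392, erythroid 0.37, stroma 0.00167 and housekeeping 0.00271. Camera gives the direction relative to all regions. Over the 42 regions named in the patch comparison and their alternatives, 0 reversed; the joint fit ended 33 calls, and leaving out 1 library up to 8. The replicate block ended 8, at Slc4a8, Gtf2i, Cd28, H2-Aa, Nfatc1, Cblb, Cd9 and Cxcr4. Library size alone ended 3, at Cblb, Adgre1 and Cxcr4, and added 2, at Cd8a and Bcl11b. Loess offsets ended 1, at Cxcr4, and added 1, at Lck. DESeq2 added 5, at Cd8a, Bcl11b, Lck, Cd79a and Prf1.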

Other observations

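The shares at gene ends and the tests within abundance and width classes were chosen after those shares or related values were seen, and the tests of other splits before.

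Some genes held several called regions in patches, a choice of genes made after their values were seen. Ms4a1 had 3 of 3 tested regions higher in B, and Rasgrp3, an activator of Ras in B cell receptor signalling, 3 of 9. Sema4f, a semaphorin, had 3 of 4 higher in T. In all, 21 genes had at least 2 regions higher in B and 14 at least 2 higher in T.

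Called regions rarely lay within 1 kb of a gene end: 19.6% of 312 higher in B and 20.4% of 269 higher in T, against 52.2% of nuclear regions not called (Fisher's exact odds ratios 0.223 and 0.236). The abundance of the regions was argued against, since within abundance classes the odds ratio was 0.146 (interval 0.117 to 0.182). Their width was argued against too, with 0.170 within width classes (interval 0.137 to 0.212). Whether the called regions are distal elements was not tested; regions are not independent replicates and gene ends are not all promoters.

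For B versus T in patches 1 of 100 splits, the real one, gave as many calls (583, highest other 0). The same held for its B cell identity list (1 of 100 permutation splits; camera p = 2.21e-24, smallest other 7.74e-19) and T cell identity list (1 of 100; 1.11e-20, smallest other 1.91e-17). These splits argue against a chance division of these libraries. They cannot address chance between animals, since the libraries were technical replicates whose animals are not known. At 100 nuclei 7 of 35 splits gave as many calls as the real 4 (highest other 4), so chance was not excluded. For the lists at 100 nuclei 1 of 35 permutation splits gave a p as small, for B cell identity (1.93e-05, smallest other 0.000267) and T cell identity (8.5e-09, smallest other 9.16e-06). For the difference between capture sizes the real count was 0 (highest other 4), so all 100 splits had to give as many and decide nothing.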
